A study of Rattus norvegicus with 8 samples.

How the data were processed

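Ventral prostate RNA of 8 TRAP rats was measured on 2-colour Agilent oligonucleotide arrays, 1 array per rat, with 4 control rats and 4 rats given telmisartan. Per the labels, the Cy5 channel held the RNA of the TRAP rat at 15 weeks of age and the Cy3 channel held a reference, normal ventral prostate of F344 rats at 6 weeks. Dyes were never swapped, so each ratio is the TRAP prostate over the reference and a dye effect is shared by all 8 arrays. Whether the reference was 1 RNA pool for all arrays is not given in the sources used here. Per the labels' protocols, RNA was extracted with ISOGEN and amplified linearly with a low input kit. The series text gives 36 rats in 3 groups; the group at 2 mg/kg per day was not analysed here. A label of the treated rats names both doses, and the series text ties the arrays to 10 mg/kg per day.

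Per the file headers, the arrays were scanned and read with Agilent Feature Extraction 9.1. The deposited scanner files give for each spot the mean pixel intensity and the median intensity of the local background in both channels, neither of them corrected. They also give a log10 ratio of Cy5 over Cy3 that, per the file headers, the software had background-subtracted, dye-normalized within the array and filled with surrogate values for weak spots. The deposited series matrix held log10 values that matched these ratios spot by spot in file order, with a largest difference of 0.00500 and a median of 0 on every array. It therefore shares their scale and direction, and it was used as an alternative. Line ends were made uniform because 2 scanner files, those of Control 106 and Telmisartan 306, broke a line with a lone carriage return.

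The intensities as deposited were background-corrected with normexp at an offset of 50 and normalized by loess within each array with control spots at weight 0, using limma 3.58.1 in R 4.3.3 with version 1.17.8 of data.table. Each array held 45018 spots, of which 43379 were gene spots and 1639 were control spots. Control spots and spots marked as outliers by the scanner software were left out, and saturated spots were kept. Spots of 1 probe were averaged to give 41012 probes. A probe was kept if it was well above background in Cy5 on at least 4 of the 8 arrays, which left 27540 probes. For testing, a probe also needed a value on all 8 arrays. Any probe whose spots were all marked as outliers on an array was therefore left out. Where several probes measured a gene, the probe with the highest mean intensity was used, which left 23188 genes for testing. Names came from a RefSeq gene table of the assembly GRCr8, used for names and gene order only. In it 10735 probes matched by accession, 5571 by current symbol and 3729 by an older symbol, and 20977 kept the name in the file. Of the genes tested, 11434 carried a gene symbol.

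Control and telmisartan rats were compared on log2(Cy5/Cy3) with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The group was the only term. Each of 32 gene lists and cell type marker lists, with at least 3 measured members, was tested with camera at a preset correlation of 0.01, adjusted over the lists. The same lists were tested with camera at an estimated correlation and with fry. The fry test asks whether the genes of a list move one way on balance, and its mixed form asks whether they change in either direction; neither compares the list with other genes. The mean log2 ratio of each list per rat was compared by an exact two-sided permutation test of 70 assignments, whose smallest p is 0.0286. Adjusted over 32 lists, that p cannot pass the threshold for a lone list. Levels over the reference are described and not tested, because strain, age, transgene and dye differ at once. The shares of spots well above background, the median Cy5 signal and the first principal component were compared by the same exact test.

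The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, in each direction, 12 genes that passed with no overlap between the groups, filled up by smallest unadjusted p where fewer passed; up to 4 members of each list by smallest unadjusted p; and a fixed set of genes that holds Agtr1a, Agtr1b, Agtr2, Ace, Agt, Pparg, Mki67, Pbsn and Cdkn1a. Some genes that the rule takes are not reported here. Names that are only accessions or predicted loci were left out by that rule. Alternatives covered background correction, normalization within and between arrays, the Cy5 channel alone, the filter on dim probes, several probes of a gene, slide, the variance model, array weights, the set test and each rat left out. An immune covariate and the omission of Control 103 and Telmisartan 302 together were added after the data were seen, as was camera with an estimated correlation in each of the other settings.

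The arrays lay on 2 slides with 2 control and 2 treated rats each, so slide can be a block. The position on the slide cannot be told apart from the group, because the treated rats took positions 1 and 2 and the control rats positions 3 and 4. The number of arrays limits the precision: the median standard error of a gene's log2 change was 0.13, against a median size of change of 0.09. The test was checked on simulated data with the spread of the 23188 genes of this comparison. It called 22.0% of genes changed by 0.5 on the log2 scale, 80.0% at 1, 96.0% at 2 and 98.0% at 3, with 50 genes at each size and 4 false calls. All sizes were planted together, which loosens the adjusted threshold, and noise was drawn independently for each gene. The real arrays share variation across genes, with 43.9% of the variance on the first principal component. These shares may therefore overstate what the test can find here.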

Results

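TRAP rats carry a transgene that drives adenocarcinoma of the prostate. Gene expression was measured in the ventral prostate of 4 untreated TRAP rats (Control 102, 103, 104 and 106) and 4 TRAP rats given telmisartan, a blocker of the angiotensin II type 1 receptor, at 10 mg/kg per day in drinking water for 12 weeks from 3 weeks of age (Telmisartan 302, 303, 305 and 306). Each prostate was set against normal F344 prostate on its own array. Well above background in Cy5 were 72.5% ± 5.63 of the spots in control rats and 62.8% ± 3.94 in treated rats (SD, n = 4 each, exact permutation p = 0.0571). In the reference channel the shares were 51.2% ± 1.47 and 49.5% ± 0.908 (exact permutation p = 0.114). The log ratios of any 2 arrays correlated across genes at 0.83 to 0.963, with means of 0.915 within control rats, 0.895 within treated rats and 0.905 between the groups.

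Control TRAP prostates were set against normal F344 prostate to describe the tumour-bearing gland. Genes of proliferation were high: 44 of 47 measured cell cycle genes lay above 2-fold in all 4 control rats, with a list median of +2.85 on the log2 scale. Mki67, the proliferation marker, averaged +3.19 ± 0.26 and E2f8, a cell cycle transcription factor, +4.76 ± 0.41 (SD, n = 4). Immune genes were also high, with list medians of +2.48 for the interferon response, +1.90 for macrophage markers, +1.72 for inflammatory cytokines, +1.71 for MHC class II and +1.5 for T cell markers. Among the highest genes were the matrix metalloprotease Mmp7 at +7.29 ± 0.16, the neutrophil chemokine Cxcl1 at +5.63 ± 0.33 and Spp1, which encodes osteopontin, at +4.90 ± 0.14.

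Secretory products of the differentiated prostate were low in the same control rats. The median of 16 measured secretory protein genes was -2.26, and 9 of them lay below 2-fold in all 4 rats. Andpro averaged -9.15 ± 0.68, Scgb1d2, a prostatein component, -7.02 ± 0.43, Msmb -6.56 ± 0.26 and the kallikrein Klk1 -6.10 ± 0.19. Azgp1, of the same list, was high at +3.92 and was the 1 member above 2-fold in all 4 rats. Skeletal muscle genes had a median of -4.14 with 13 of 13 below 2-fold, adipocyte genes -2.87 and smooth muscle genes -0.93. In all, 1204 genes lay above and 970 below 2-fold in all 4 control rats, and 865 and 763 did so in all 8 rats. These levels carry no test, since the reference differs from the TRAP rats in strain, age, transgene and dye together.

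**Figure D1:**
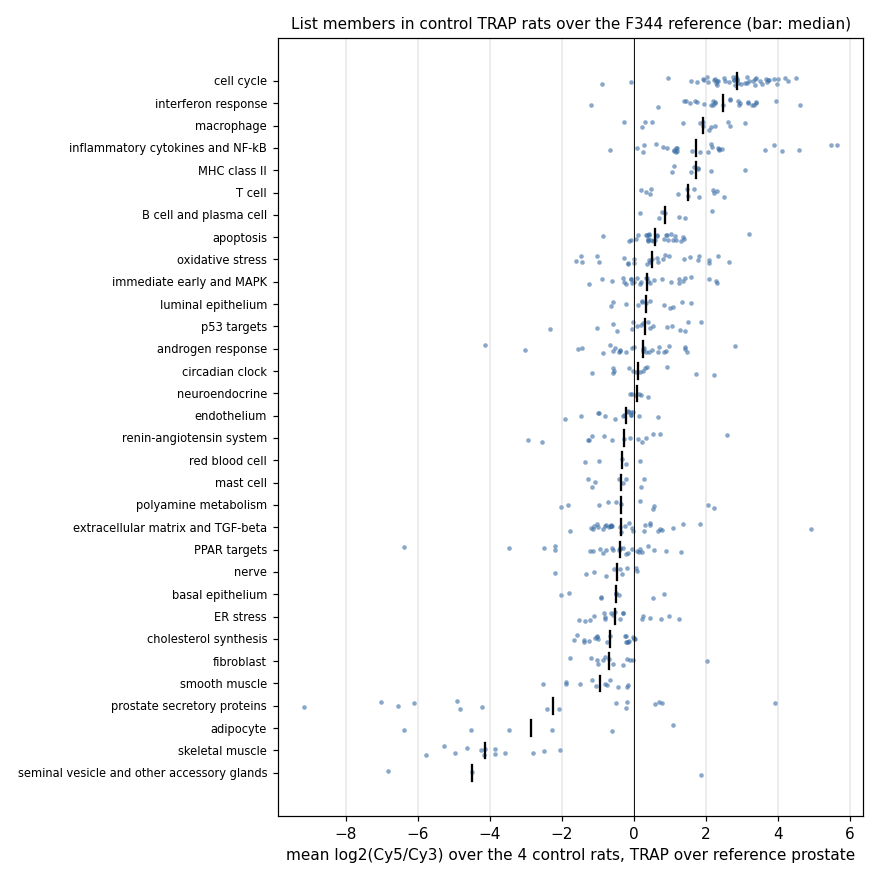
Mean log2(Cy5/Cy3) of each measured member of the 32 gene lists over the 4 control rats, TRAP prostate over the F344 reference prostate; each point is a gene and the bar is the list median. Cell cycle genes lie highest with a median of +2.85, and secretory protein genes have a median of -2.26.

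The comparison of telmisartan with control rats asks which genes the drug changes in the tumour-bearing prostate. The gene closest to the threshold among those higher in treated rats was Med17, which encodes a subunit of the Mediator complex of transcription, at -1.32 ± 0.17 in control and -0.13 ± 0.27 in treated rats, a 2.28-fold difference (log2 +1.19, SE 0.15, n = 4 each, limma adjusted p = 0.288). Among those lower, Cd55, an inhibitor of complement on the cell surface, differed by log2 -0.97 (SE 0.14, adjusted p = 0.619) and Tnfrsf11b, the secreted decoy receptor osteoprotegerin, by -1.0 (SE 0.16, adjusted p = 0.763). None of the 23188 genes passed in limma: 0 were higher and 0 were lower, and the fits with array weights and with a trended, robust variance also gave 0. At an unadjusted p under 0.05 there were 636 higher and 481 lower genes, 1117 in all, against 1159 expected by chance; with slide as a block there were 796 and 616, 1412 in all. The groups did not overlap for 632 genes, or 2.73%, where chance gives 2.86%.

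Genes without a gene symbol were left out of this ranking. Of the others, the 12 with the smallest p among those higher in treated rats had log2 changes of +0.39 to +1.19. Beside Med17 they included Rimbp2, a scaffold of the presynaptic active zone, at +1.05 (SE 0.22), for which a second probe also gave +1.05. Dapl1 was at +0.78 (SE 0.16), Ddit4l, an inhibitor of mTOR signalling, at +0.72 (SE 0.16), and Cyp26b1, which degrades retinoic acid, at +0.46 (SE 0.10). Sytl3, which acts in vesicle release, stood at +0.63, the selenium-binding protein gene Selenbp1 at +0.52, the metalloprotease gene Adam28 at +0.50 and Slc17a5, the lysosomal sialic acid exporter, at +0.39. The deposited series values gave +0.95 for Adam28. Kiaa0408L at +0.63, Kctd14 at +0.61 and C8h11orf65 at +0.47 complete them. A second Kiaa0408L probe, well above background on 0 arrays, gave -0.17. On slide 1 and slide 2 alone Med17 was at +1.27 and +1.10, Rimbp2 at +1.10 and +1.00, and Dapl1 at +0.86 and +0.71. For all 12 genes every treated value lay above every control value. Their sign on each slide follows from that and is no separate support.

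Among genes with a symbol, the 12 with the smallest p of those lower in treated rats ranged from -0.44 to -1.0. Among those of the matrix, Ccn2, a matricellular growth factor, was at -0.94 (SE 0.21) and P4ha1, a subunit of the enzyme that hydroxylates collagen prolines, at -0.48 (SE 0.10). The immediate early transcription factor Egr2 was at -0.80 (SE 0.20), the endosomal sorting nexin Snx10 at -0.80 (SE 0.19) and the adrenergic receptor gene Adra1d at -0.52 (SE 0.12). Caps2 at -0.48, Rapgef5 at -0.46, Arhgef6 at -0.45 and Lhx2 at -0.44 were also among them. On slide 1 and slide 2 alone Cd55 was at -1.06 and -0.88, Tnfrsf11b at -1.30 and -0.71, and Ccn2 at -1.08 and -0.81. For all 12 genes every treated value lay below every control value, which fixes the sign on each slide. Arhgef6 was well above background on 1 and Lhx2 on 2 of the 4 treated arrays, and the Cy3 reference of Lhx2 was higher on treated arrays by 0.43, with a Cy5 difference of -0.005; normalised by itself, the Cy5 channel gave +0.12 for Lhx2, -0.44 for Snx10 and -0.16 for Arhgef6. The scanner's own ratios gave -1.21 for Snx10 and -0.83 for Arhgef6. A second Arhgef6 probe, well above background on 0 arrays, gave -0.10.

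**Figure D2:**
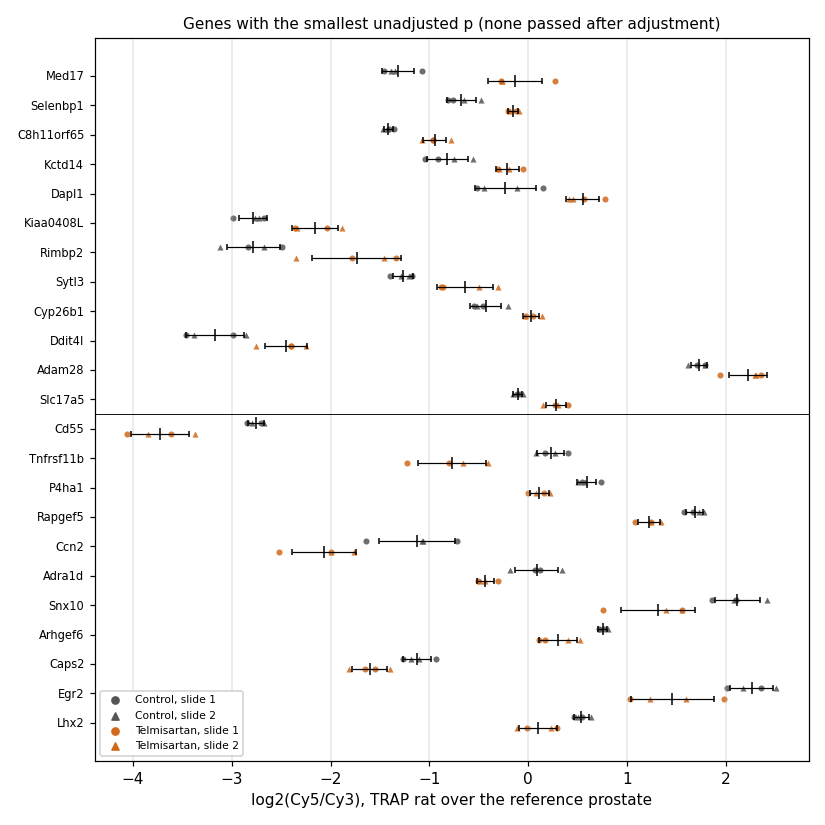
Log2(Cy5/Cy3) per rat for the named genes with the smallest unadjusted p in each direction, TRAP prostate over reference; circles are rats of slide 1 and triangles rats of slide 2, and bars give the mean ± SD of the 4 rats of a group. Med17 averages -1.32 in control and -0.13 in treated rats and Cd55 -2.76 and -3.73, and no gene passed after adjustment.

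Immune genes were lower on average in treated rats, and the spread between rats was larger than the difference. All 27 measured interferon response genes were lower, with a mean of 2.41 ± 0.62 in control and 1.91 ± 0.79 in treated rats (difference -0.50, exact permutation p = 0.314, n = 4 each); among them were the chemokine Cxcl11 at -1.18 (SE 0.65), Ifit2 at -1.33 (SE 0.74) and Oas1a at -0.46 (SE 0.26). Of 28 inflammatory cytokine and NF-kB genes 26 were lower (mean -0.51, exact permutation p = 0.371), including the monocyte chemokines Ccl7 at -1.38 (SE 0.57) and Ccl2 at -1.46 (SE 0.80), Cxcl10 at -1.16 (SE 0.66) and Il1rn at -0.77 (SE 0.44). All 8 MHC class II genes were lower (mean -0.54, exact permutation p = 0.286), among them RT1-Ba at -0.74, RT1-Bb at -0.61, Ciita, the class II transactivator, at -0.51 and Ctss at -0.43. With the mean of a gene's probes RT1-Ba stood at -0.06 and RT1-Bb at +0.38. Of 13 T cell markers 12 were lower (mean -0.45, exact permutation p = 0.314), with Cd8b at -0.72, Cd2 at -0.76, Cd3d at -0.87 and Cd5 at -0.47. Of 14 macrophage markers 12 were lower (mean -0.33, exact permutation p = 0.4), with Itgam at -0.55 (SE 0.16), Mrc1 at -0.46 (SE 0.14), Cd68 at -0.42 and Tyrobp at -0.44.

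Camera with a preset correlation of 0.01 called these 5 immune lists lower. The adjusted p was 2.41e-05 for the interferon response and cytokines, 0.00261 for MHC class II, and 0.00396 for T cell and macrophage markers. The correlation between genes estimated from the data was 0.87, 0.74, 0.88, 0.69 and 0.70 in the same order. The preset is far below these values, so its adjusted p overstates the evidence. Each call was lost with an estimated correlation (adjusted p = 0.848), which called 0 of the 32 lists here and in each of 24 other settings (smallest adjusted p = 0.379), so every gained call below rests on the preset one. Fry (adjusted p = 0.942) and its mixed form (adjusted p = 0.729) called none. No member passed over all genes, and 0 passed adjusted over the list alone. With slide as a block the differences were the same, since each slide holds 2 rats of either group. Within slide 1 the interferon difference was -0.90, cytokines -0.80, MHC class II -0.66, T cell -0.62 and macrophage -0.43; within slide 2 they were -0.10, -0.22, -0.41, -0.28 and -0.23. Without Telmisartan 302, the rat with the lowest immune levels, camera called 2 of the 32 lists instead of 8 and none of the immune ones, which then stood at -0.20, -0.13, -0.21, -0.22 and -0.07. Without Control 103 they stood further from 0, with -0.80 for the interferon response, -0.87 for MHC class II, -0.75 for T cell and -0.55 for macrophage markers, and all 5 were called; all 5 were also called with both of these rats left out. Without Telmisartan 305 the interferon list was at -0.80, T cell at -0.69 and macrophage at -0.52. The macrophage call was also lost without Control 102 (adjusted p = 0.0536) or Control 106 (0.114), and the T cell call without Control 102 (0.146) or Control 104 (0.0708). The interferon call was lost on slide 2 alone (0.597), and that of MHC class II with the mean of a gene's probes (-0.31, 0.0902). With the immune covariate the interferon list stood at -0.008 (camera adjusted p = 0.921) and cytokines at -0.06 (0.699), and both calls were lost. The covariate is made of the T cell, macrophage and MHC class II markers, so their own lost calls with it are no evidence.

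Extracellular matrix and TGF-beta genes were lower on average, 22 of 32 with a mean of -0.19 and a median of -0.09 (-0.06 ± 0.04 in control and -0.26 ± 0.25 in treated rats, exact permutation p = 0.257, n = 4 each). At an unadjusted p under 0.05, 7 members were lower and 0 higher; 4 were lower adjusted over the list alone, among them Ccn2, Ltbp1, which holds latent TGF-beta in the matrix, at -0.77 (SE 0.20) and Thbs2, a thrombospondin, at -1.07 (SE 0.29), and 0 over all genes. Immediate early and MAPK genes were lower for 23 of 28, with a mean of -0.23 and a median of -0.12 (0.50 ± 0.09 and 0.27 ± 0.17, exact permutation p = 0.0571). Of these, Egr2 and Egr1 at -0.91 (SE 0.24) were the 2 lower adjusted over the list alone, and Ccn1 was at -0.61 (SE 0.21), Btg2 at -0.50 (SE 0.18) and Fos at -0.39 (SE 0.16). Camera called both lists lower (adjusted p = 0.00313 for matrix and 0.000310 for immediate early genes). Both calls were lost with an estimated correlation, 0.26 and 0.11 (adjusted p = 0.848), and with fry (adjusted p = 0.942, mixed form 0.729). Relative to the control mean the matrix list stood at -0.44 in Telmisartan 302, +0.09 in Telmisartan 303, -0.06 in Telmisartan 305 and -0.36 in Telmisartan 306. Its call was lost without Telmisartan 302 (-0.11, adjusted p = 0.371), without Telmisartan 306 (-0.14, adjusted p = 0.073), on slide 1 alone (adjusted p = 0.053) and with a covariate for immune markers (-0.13, adjusted p = 0.224), and with Control 103 and Telmisartan 302 both left out (-0.11, adjusted p = 0.448). The immediate early call held with any 1 rat left out. Within slide 1 and slide 2 the matrix difference was -0.16 and -0.22, and the immediate early difference -0.25 and -0.21.

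Markers of stromal and other cell types were measured beside them, and camera called none of these lists with the settings used throughout. Fibroblast markers, of which 5 are also matrix genes, averaged -0.10 (exact permutation p = 0.457, camera adjusted p = 0.276), with 8 of 13 lower; Mfap5, a microfibril protein gene, was at -0.56 (SE 0.16), Sfrp2 at -0.35, Col1a1 at -0.30 and Dpt at -0.25. On slide 1 and slide 2 Sfrp2 was at -0.88 and +0.18, and Col1a1 at +0.08 and -0.67. Smooth muscle markers averaged +0.13 (exact permutation p = 0.457, adjusted p = 0.0708), with Tpm2 at +0.56, Myh11 at +0.39, Mylk at +0.33 and Casq2 at +0.27; the list stood at +0.36 on slide 1, where camera called it, and -0.11 on slide 2. It was also called without Control 104 (+0.18), Control 106 (+0.17), Telmisartan 303 (+0.14) or Telmisartan 305 (+0.18) and with median centring (+0.21), and stood at +0.04 without Control 102 and +0.05 without Telmisartan 302. Endothelial markers averaged -0.03 (adjusted p = 0.988; Kdr -0.76, SE 0.55; Cldn5 +0.19; Pecam1 +0.23 and Robo4 +0.13, each well above background on 1 of 4 treated arrays). Basal epithelial markers averaged +0.15 (adjusted p = 0.276), with the keratin gene Krt15 at +0.72 (SE 0.30), Tp63 at +0.50, Jag2 at +0.16 and Dst at -0.17. The basal list was called on slide 1 alone (+0.21), without Control 104 (+0.25) and with the immune covariate (+0.33), and stood at +0.02 without Control 103, +0.05 without Telmisartan 305 and +0.07 with array weights. The fibroblast list was called without Telmisartan 305 (-0.17, adjusted p = 0.0456), and stood at -0.01 without Telmisartan 306, -0.002 in the Cy5 channel alone and +0.01 with median centring. Luminal epithelial markers averaged -0.05 (adjusted p = 0.655), with Prom1 at -0.34, Cldn4 at -0.29, Krt18 at +0.20 and Foxa1 at +0.18.

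Apoptosis genes were lower for 21 of 29, with a mean of -0.14 (0.68 ± 0.12 in control and 0.55 ± 0.15 in treated rats, exact permutation p = 0.229, n = 4 each). The list as fixed holds inhibitors of cell death, such as Bcl2, Mcl1 and Xiap, beside its promoters. A lower mean therefore gives no direction for cell death. Camera called the list lower (adjusted p = 0.00275). With an estimated correlation, 0.16, its adjusted p was 0.848, and fry gave 0.942 (mixed form 0.729). Of its members, 0 passed over all genes or adjusted over the list alone. Relative to the control mean Telmisartan 302, 303, 305 and 306 stood at -0.35, -0.12, +0.02 and -0.09. The call was lost without Telmisartan 302 (-0.07, adjusted p = 0.239), without Control 102 (-0.10, 0.0536), on slide 2 alone (0.128), with median centring (-0.08, 0.0597) and with the immune covariate (-0.04, 0.521). Cycs, the cytochrome of the apoptosome, was at -0.27 (SE 0.09), Bbc3, which encodes Puma, at -0.34 (SE 0.16) and Apaf1 at -0.24 (SE 0.11). The list moved with immune markers across the 8 rats: its mean correlated with the mean of the T cell, macrophage and MHC class II lists at Pearson r = 0.981 (exact permutation p = 4.96e-05, 0.00108 adjusted over 29 lists) and Spearman rho = 0.976 (exact permutation p = 0.000397). Without Control 103 and Telmisartan 302, the rats farthest from the median, r was 0.980, and with slide means removed it was 0.978, each slide holding too few rats for an r of its own. The immediate early list gave r = 0.846 and rho = 0.857 (exact permutation p = 0.0061 and 0.0107, adjusted p = 0.0243; 0.838 without the same rats; 0.851 with slide means removed). Random lists were not compared, so neither correlation is shown to be particular to its list. Within slide 1 the apoptosis difference was -0.20 and within slide 2 -0.07.

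Cell cycle genes differed by less than the spread between rats: the mean was 2.78 ± 0.19 in control and 2.73 ± 0.20 in treated rats (difference -0.05, exact permutation p = 0.6, n = 4 each; camera adjusted p = 0.293). Mki67 was at +0.06 (SE 0.14), cyclin D1 (Ccnd1) at -0.47 (SE 0.36), Ccna2 at -0.21 (SE 0.20), and the replication helicase genes Mcm5 at +0.22 and Mcm3 at -0.12. The list was at -0.07 on slide 1 and -0.03 on slide 2. Camera called it lower without Control 102 (-0.11, adjusted p = 0.0106), without Telmisartan 302 (-0.14, adjusted p = 0.000347) and with the immune covariate (-0.18, adjusted p = 5.21e-09). With an estimated correlation, 0.57 for this list with all rats, these calls were lost (adjusted p = 0.932, 0.935 and 0.812). It stood at +0.04 without Control 103 and at +0.01 without Telmisartan 303, with median centring, with scaling between arrays and in the Cy5 channel alone, uncalled in each. For p53 targets the mean was -0.09 (camera adjusted p = 0.276; -0.15 and called without Telmisartan 303, adjusted p = 0.0212; -0.0004 without Telmisartan 302), with Btg2 at -0.50, Plk3 at -0.37, Perp at +0.21 and Cdkn1a, the p21 cell cycle inhibitor, at -0.21 (SE 0.14). No member of either list passed over all genes or adjusted over the list alone.

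Prostate secretory protein genes were higher for 10 of 16, with a mean of +0.11 and a median of +0.16 (exact permutation p = 0.314, camera adjusted p = 0.132; +0.06 on slide 1 and +0.17 on slide 2). Camera called the list higher on slide 2 alone (adjusted p = 0.0299), with median centring (+0.22, 0.0386) and without both Control 103 and Telmisartan 302 (+0.22, 0.0106), and it stood at +0.06 without Telmisartan 303. Scgb1d2 was at +0.81 (SE 0.22), Scgb1d4 at +0.44 (SE 0.15) and Sbp, the spermine-binding protein gene, at +0.30 (SE 0.10), while Pbsn, which encodes probasin, was at -0.36 (SE 0.19). Of the 3 measured seminal vesicle and accessory gland genes, Svs4 was at +0.63 (SE 0.18) and was the 1 gene higher adjusted over the list alone, with Ceacam4 at -0.86 and Semg1 at -0.11; the list mean was -0.12 and camera gave adjusted p = 0.988. Androgen response genes averaged -0.01 (adjusted p = 0.718), with 15 of 29 higher and 14 lower. Among those with the smallest p were Mboat2 at +0.56 (SE 0.16), Camkk2 at +0.35 (SE 0.14) and Slc45a3 at +0.23.

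The genes of the drug's own target system did not pass. Agtr1a, which encodes the receptor that telmisartan blocks, was -0.82 ± 0.08 in control and -0.70 ± 0.16 in treated rats (log2 change +0.13, SE 0.11), and the probes of Agtr1b and Agtr2 were well above background on 0 of the 8 arrays. Angiotensinogen (Agt) was at +0.06 (SE 0.09), the converting enzyme Ace at -0.08 (SE 0.13), Enpep, the aminopeptidase that trims angiotensin II, at -0.84 (SE 0.28), Mme at +0.41, Atp6ap2 at -0.20 and Nr3c2 at +0.19. With the mean of a gene's probes Enpep stood at -0.48. The 15 measured genes of the system averaged -0.03 (adjusted p = 0.988). PPAR target genes, included because telmisartan also activates PPAR gamma in part, averaged -0.04 (adjusted p = 0.988), with Pparg at -0.23 (SE 0.27), Cd36 at -0.49, Lpl at -0.41 and Cpt1a at +0.20.

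Other metabolic and stress lists were not called by camera with the settings used throughout and had no member that passed over all genes or adjusted over the list alone. Oxidative stress genes averaged -0.07 (adjusted p = 0.537, and -0.002 without Telmisartan 302), with 18 of 27 lower. Those with the smallest p were the glutathione enzymes Gstm1 at +0.39, Mgst1 at +0.28 and Gpx4 at +0.17, and Nox1 at +0.17. The scanner's own ratios gave -0.62 for Nox1. ER stress genes averaged -0.07 (adjusted p = 0.451), with the stress-induced Chac1 at -0.33, Trib3 at -0.54 and Ddit3 at -0.37 and the folding enzyme Pdia3 at +0.21. The ER stress list was at +0.03 on slide 1 and -0.17 on slide 2, where camera called it (adjusted p = 0.00472); it was also called without both Control 103 and Telmisartan 302 (-0.14, 0.0362), and stood at -0.01 without Control 104. Polyamine genes averaged -0.04 (adjusted p = 0.907), with Arg1, arginase, at -0.90 (SE 0.32), Odc1 at +0.30, Amd1 at +0.19 and Srm at +0.11. Cholesterol synthesis averaged +0.004 (adjusted p = 0.988; Lss +0.41, Hmgcs1 -0.29, Fdft1 +0.20) and circadian clock genes -0.02 (adjusted p = 0.750), with the clock repressors Per3 at +0.37 (SE 0.12), Nr1d1 at +0.29, Per1 at +0.23 and Bhlhe41 at -0.63.

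The remaining cell type markers were not called with the settings used throughout either. B cell and plasma cell markers averaged -0.19 (adjusted p = 0.235), with 7 of 7 lower, including Tnfrsf17 at -0.42, Mzb1 at -0.29, Jchain at -0.26 and Cd22 at -0.24. The B cell list was called on slide 1 alone (-0.43) and without Control 103 (-0.31), Telmisartan 305 (-0.34) or Telmisartan 306 (-0.28), and stood at -0.04 without Telmisartan 302 and +0.04 on slide 2. Mast cell markers averaged -0.10 (adjusted p = 0.508; Mcpt1 -0.49, Kit -0.19, Ms4a2 -0.11, Hdc -0.09), adipocyte markers -0.16 (adjusted p = 0.276; Cfd -0.63, Fabp4 -0.30, Adipoq -0.11, Cidea +0.11) and red blood cell markers -0.27 (adjusted p = 0.115; Ahsp -0.88, Hemgn -0.27, Alas2 -0.10, Hbb -0.08). The red blood cell list was called with median centring (-0.31, adjusted p = 0.0102), in the Cy5 channel alone (-0.30, 0.0465), with the immune covariate (-0.37, 0.0473), on slide 2 alone (-0.40, 0.00683) and without Control 102 (-0.43, 0.00167), and stood at -0.14 on slide 1. Skeletal muscle markers averaged +0.002 (adjusted p = 0.852; Mb -0.17, Tnnt3 -0.19, Acta1 +0.12, Tnni2 -0.16). Neuroendocrine markers averaged -0.005 (adjusted p = 0.988), with Ncam1 at -0.12, Pcsk1 at +0.29, Eno2 at -0.21 and Chga at -0.11. Nerve markers averaged +0.06 (adjusted p = 0.359), with Prx at +0.26, Nefm at +0.16, Mbp at +0.14 and Nefl at +0.13; the list was called on slide 1 alone (+0.22, with -0.10 on slide 2) and without Control 104 (+0.14).

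For several uncalled lists the mean, the median and the direction of the camera test differ in sign. The camera direction was up against a mean below 0 for androgen response, PPAR target, polyamine, circadian clock, endothelial and seminal vesicle genes. It was down against a mean above 0 for skeletal muscle genes. The medians of the androgen response, renin-angiotensin and polyamine genes were above 0 against means below 0, and those of the cholesterol synthesis and skeletal muscle genes below 0 against means above 0. Over the alternatives the means lay on both sides of 0, uncalled, for androgen response (-0.04 to +0.05), PPAR target (-0.08 to +0.04), cholesterol synthesis (-0.10 to +0.09), luminal (-0.11 to +0.05), endothelial (-0.15 to +0.07) and mast cell genes (-0.23 to +0.11). The same held for renin-angiotensin, polyamine, circadian clock, skeletal muscle, seminal vesicle and neuroendocrine genes.

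Of 146 named genes 15 had opposite signs on slide 1 and slide 2. Beside Sfrp2 and Col1a1 they were Jchain (-0.91 and +0.38), Myh11 (+0.81 and -0.03), Nefm (+0.55 and -0.22), Cldn5 (+0.40 and -0.01), Acta1, Nefl, Mbp, Semg1, Cidea, Srm, Hdc, Ace and Mki67. With these, 27 turned with at least 1 alternative, such as Pecam1 at -0.34 and Nox1 at -0.26 in the Cy5 channel alone. Probes well above background on 1 or 2 arrays of a group also included those of Nox1, Kit and Hemgn (2 treated arrays each), Chga and Mbp (1 treated array each) and Nefl (2 control arrays).

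**Figure D3:**
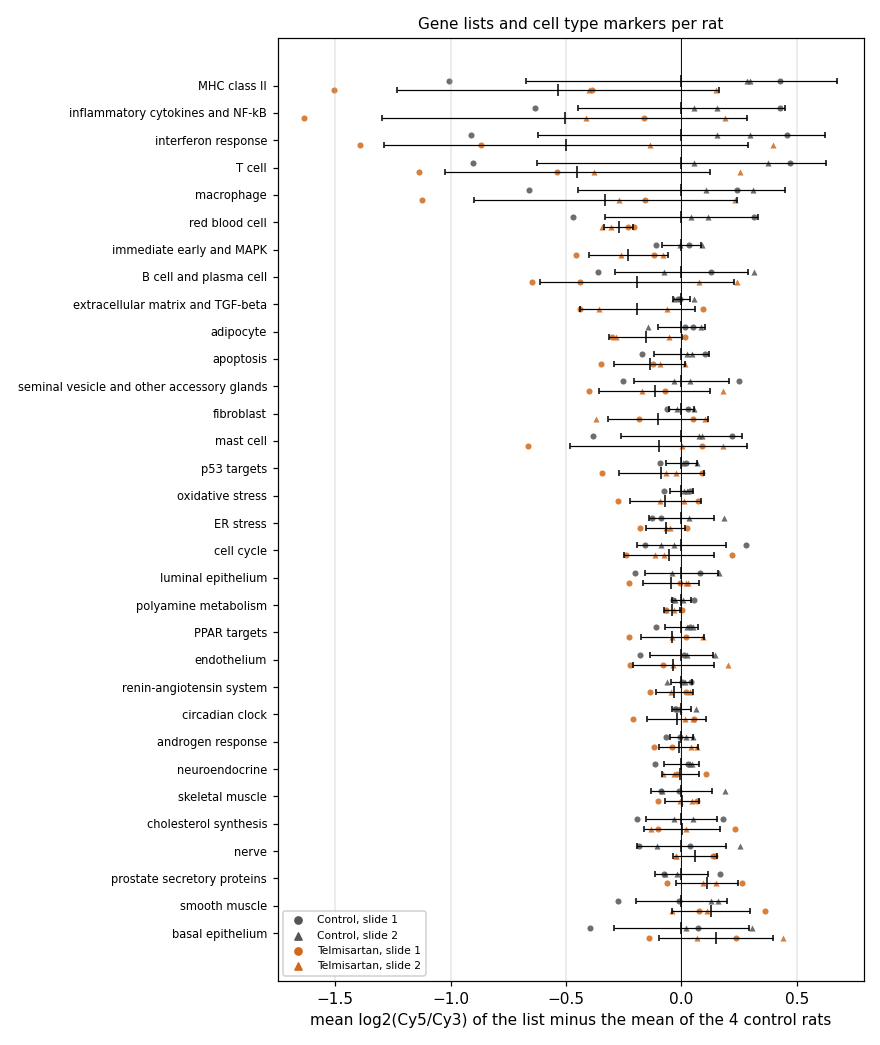
Mean log2(Cy5/Cy3) of each of the 32 lists per rat, minus the mean of the 4 control rats; circles are rats of slide 1 and triangles rats of slide 2, and bars give the mean ± SD of the 4 rats of a group. The immune lists spread most between rats, and the mean difference is -0.54 for MHC class II and -0.23 for immediate early genes.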

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

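Chosen after the results were seen were the tests of the splits for the count of genes, for the immune difference and within slides, of the stromal marker lists of the fibroblast markers outside the matrix list and of the Cy5 channel for the array position, and the immune covariate itself. Splits of the 8 rats into 4 against 4 bear on the gene and list counts. Of 35 splits, all 35 gave at least the 0 genes of the real split, which holds by construction. Of them, 6 called a gene, and the highest of the others called 933. That split had Control 102, 104 and 106 and Telmisartan 305 on 1 side, the rats highest in T cell, macrophage and MHC class II markers. It also gave the highest immune difference below, 1.0, which points to a structure of the samples. For genes at an unadjusted p under 0.05, 16 of 35 splits gave as many as the 1117 of the real split, with a highest other of 4421. For lists called by camera, 14 of 35 gave as many as 8, with a highest other of 18. Chance can be excluded for neither of these 2 counts, and the count of 0 genes says nothing on it. The split that follows slide gave 100 genes, 3504 genes at an unadjusted p under 0.05 and 7 lists, and with slide as a block the real split gave 0 genes. With slide as a block and 2 rats of either side on each slide there are 18 splits, too few for a share under 0.05: the real split gave 1412 genes at an unadjusted p under 0.05 (7 of 18 gave as many, highest other 2237) and 8 lists (9 of 18, highest other 18). Whether immune variation between rats hides changes stays open: 0 genes passed with the immune covariate, which the prediction had set as evidence against it. That prediction was set aside after the values were seen, because genes at an unadjusted p under 0.05 went from 636 higher and 481 lower to 750 and 829. The cell cycle, basal epithelial and red blood cell lists became called with the preset correlation only (adjusted p = 0.812, 0.805 and 0.805 with an estimated one).

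The immune lists averaged lower in treated rats by -0.47 over 89 members (exact permutation p = 0.343), and 12 of 35 splits gave a difference as large, with a highest other of 1.0, so chance cannot be excluded; leaving out only Telmisartan 302 gave -0.16, only Control 103 -0.74 and only Telmisartan 305 -0.72. The tables argue against the reference channel as the cause, since the Cy3 difference of these members was -0.069. Weaker signal on the treated arrays was predicted to leave a smaller difference in bright members. Those above the median brightness differed by -0.47 (SE 0.46), 0.999 times as much as all members. Both differences lie within their spread between rats, so this ratio cannot rule out weaker signal. The array position follows the group and cannot be told apart from it, and the Cy5 difference was -0.54. A smaller share of all non-epithelial cells stays open. The mean of the stromal lists differed by -0.00294 (SE 0.061), but the lists behind it went different ways. Smooth muscle stood at +0.13, fibroblast at -0.10 and endothelium at -0.03. The immune difference itself also lies within its spread between rats (SE 0.44). An effect of telmisartan on immune cells or their genes may also contribute and remains untested beyond these values.

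The 24 genes with the smallest p among those with a gene symbol, led by Med17, Cd55 and Tnfrsf11b, were weighed next. For the 24 as a set the reference channel is an unlikely cause, since the median Cy3 difference was -0.0121 of the change in log ratio; Lhx2, with a Cy3 difference of +0.43 against a change of -0.44, Snx10, with +0.37, and Arhgef6, with +0.27, go the other way. Inherited differences between rats of the groups would place such genes side by side on a chromosome. Among the 200 genes with the smallest p, 2 pairs were neighbours, against a median of 1 and a 95th percentile of 2 in 10000 random draws, but only 47.5% of the 200 had a position, so this test is void. A response of these genes to telmisartan stays open, as do chance and the array position, which follows the group (median Cy5 difference 0.988 of the change).

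Matrix and immediate early genes, such as Ccn2, Thbs2, Egr1 and Egr2, averaged lower in treated rats. Fewer fibroblasts cannot be told apart from a change within cells: the 8 fibroblast markers outside the matrix list had a median of -0.067, with 5 lower and 3 higher. With the immune covariate the mean change of the lists was 0.648 of that without it. The markers of the covariate were themselves lower on average in treated rats. This drop therefore cannot tell immune variation between rats from an effect of telmisartan. The matrix list went from -0.19 to -0.13 (camera adjusted p = 0.224) and the immediate early list from -0.23 to -0.14 (camera adjusted p = 0.0473). Both keep an effect of telmisartan as an open and untested explanation.

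Single rats stood far from the other 3 of their group in 5 of 64 group values of lists, 16 of 292 of genes and 3 of 10 of array measures; chance does this in about 1 of 20 groups. Control 103 did so 6 times, Telmisartan 302 5 times, Telmisartan 303 and Telmisartan 305 4 times each, Control 102 3 times, and Control 104 and Control 106 1 time each. Control 103 was lowest for MHC class II at 0.77, where the others began at 2.05, and for PPAR targets at -0.89, Cd68 at 1.75 and Cd5 at 0.43. It was highest for Atp6ap2 at 1.04 and on the first principal component at 30.3, where the other control rats lay between -23.5 and -19.3. Telmisartan 302 was lowest for circadian clock genes at 0.0016, luminal epithelial markers at 0.21, Bbc3 at 0.10 and Cldn4 at 0.25, and its array correlated least with the others, at a mean of 0.856. Control 102 was lowest for neuroendocrine markers at -0.018, Fdft1 at -1.30 and Krt18 at 0.016. Telmisartan 303 was highest for Med17 at 0.28 and Alas2 at -0.93, lowest for Adam28 at 1.94, and had the lowest share of Cy3 spots well above background, 48.2%. Telmisartan 305 was lowest for Lss at -1.39 and highest for Prom1 at 0.11, Mb at -2.92 and Hemgn at 0.26. Control 104 was highest for Jag2 at -0.11, and Control 106 lowest for Adipoq at -6.57.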

How the results depend on the processing

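The immune covariate, the omission of Control 103 and Telmisartan 302 together, and the estimated correlation within each other setting were alternatives chosen after seeing the data. Over the alternatives to all 8 rats, limma called 0 genes in either direction. Leaving out 1 rat at a time gave 0 to 1 higher and 0 to 1 lower genes: without Control 102, 1 expressed sequence tag with no gene symbol was higher (log2 +1.48, adjusted p = 0.0075; +1.17 and 0.886 with all rats), and without Telmisartan 303 another was lower (-2.02, adjusted p = 0.00591; -1.54 and 0.923 with all rats), where the left-out rat lay away from its group. In the other alternatives the smallest adjusted p lay between 0.0834 and 0.999. Lists called by camera, 8 with all rats, numbered 2 to 11 with 1 rat left out, 2 being without Telmisartan 302, and 4 with the immune covariate. An estimated correlation called 0 (also in each of 24 other settings, smallest adjusted p = 0.379) and fry called 0. Both weigh the correlation or spread between rats. Permutation of the list means also called 0. That count says little, because its smallest p of 0.0286, adjusted over 32 lists, cannot pass for a lone list. Of 863 list values, 702 kept direction and call, 49 lost and 30 gained a call, and 81 uncalled ones changed sign. Calls were gained by smooth muscle in 6 of 27 alternatives, red blood cell in 5, B cell in 4 of 26, cell cycle, prostate secretory and basal epithelium in 3 each, ER stress and nerve in 2 each, and fibroblast and p53 in 1 each. The macrophage list turned to +0.036 with the immune covariate, which holds its own genes. Of 3658 values of named genes, 3596 kept their direction, and 62 of 27 uncalled genes changed sign. Of the 24 genes with a symbol and the smallest p, 23 kept theirs, and Lhx2 turned in the Cy5 channel alone. The groups do not overlap for these 24, so their sign on 1 slide or without 1 rat could not change. Genes at an unadjusted p under 0.05, 636 higher and 481 lower, moved most in the settings that follow. They were array weights (1320 and 1277), slide as a block (796 and 616) and the immune covariate (750 and 829). Slide 1 only gave 249 and 217, and slide 2 only gave 732 and 637. With Control 103 and Telmisartan 302 both left out there were 981 and 1222. Single rats left out were Control 103 (784 and 1237), Telmisartan 302 (832 and 625), Telmisartan 305 (870 and 888) and Telmisartan 306 (397 and 268). No filter on dim probes gave 1056 and 903, but among 35302 genes tested in place of 23188. The Cy5 channel alone gave 766 and 314, 70.9% higher against 56.9%, and median centring without loess 603 and 312, 65.9% higher. Where no construction is named the cause was not tested. Signal over background limits genes such as Arhgef6, and with probes above background on all 8 arrays 19300 genes were tested and 0 passed. No paired analysis was possible because the groups share no replicate numbers.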

Other observations

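Cytotoxic lymphocyte and interferon genes were among the genes that varied most between rats of 1 group, and they were picked for this after their values were seen. Gzmb, a granzyme of killer cells, was at 3.81, 1.05, 4.0 and 2.47 in Control 102, 103, 104 and 106 and at 0.33, 0.54, 3.52 and 1.58 in Telmisartan 302, 303, 305 and 306. Prf1, which encodes perforin, was at 2.99, 0.01, 2.70 and 1.86 and at 0.18, 0.38, 2.76 and 1.17 in the same order, and the antiviral gene Rsad2 at 5.29, 3.19, 5.35 and 4.54 and at 1.53, 2.52, 5.31 and 4.43. The neutrophil chemokine Cxcl2 was lowest in Telmisartan 302 at 1.28, with 4.52 to 6.65 in the other rats, and its reference signal was well above background on 1 array only. Other genes varied apart from these. Gys2, the glycogen synthase of liver, was at -0.08 in Control 102 and between -5.44 and -5.07 in the other control rats, and between -3.42 and 0.85 in treated rats. Nqo2, a quinone reductase, was at -0.42 in Control 106 and -0.38 in Telmisartan 306, and between -3.47 and -2.98 in the other rats; Rec114, a meiotic recombination gene, was at 2.07 and 1.03 in the same rats and between -2.26 and -1.26 in the others. The files of these 2 arrays are those whose line ends were repaired; the repaired lines held other probes, and the deposited series values of Nqo2 were -0.56 and -0.50 there and those of Rec114 2.28 and 1.14.

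Across the 8 rats 12 of 29 lists moved with the mean of the T cell, macrophage and MHC class II markers at an adjusted p under 0.05, apoptosis and immediate early genes among them. The first principal component held 43.9% of the variance. It was highest in Telmisartan 302 at 44.8 and Control 103 at 30.3, the rats lowest in these markers. Random lists were not compared, so none of these relations is shown to be particular to its list. Endothelial markers gave r = 0.882 and rho = 0.833 (exact permutation p = 0.0038 and 0.0154, adjusted p = 0.0183), with 0.666 without Control 103 and Telmisartan 302 and 0.846 with slide means removed. The seminal vesicle and accessory gland list, of 3 genes, gave r = 0.933 and rho = 0.952 (exact permutation p = 0.000149 and 0.00114, adjusted p = 0.00108), with 0.82 without the same rats and 0.96 with slide means removed. Ceacam4, which the array calls Ceacam10, varied most in it (SD 0.81 in control and 0.99 in treated rats). The interferon response gave r = 0.955 and rho = 0.976 (exact permutation p = 7.44e-05 and 0.000397, adjusted p = 0.00108), with 0.879 without these rats and 0.943 with slide means removed. Cytokine genes gave 0.953 and 0.952 (0.000149 and 0.00114, adjusted p = 0.00108; 0.923; 0.955), PPAR targets 0.926 and 0.786 (0.00179 and 0.0279, adjusted p = 0.0104; 0.657; 0.897) and B cell markers 0.861 and 0.881 (0.0067 and 0.00724, adjusted p = 0.0243; 0.64; 0.805), in the same order of values.

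Other relations rest more fully on Control 103 and Telmisartan 302, though the endothelial, PPAR target and B cell ones above also weakened without them. No p was computed for r without these rats. Cholesterol synthesis went the other way, with r = -0.815 and rho = -0.69 (exact permutation p = 0.0146 and 0.0694, adjusted p = 0.0373), -0.279 without these rats and -0.866 with slide means removed. Mast cell markers gave 0.85 and 0.619 (0.0106 and 0.115, adjusted p = 0.0327; -0.0966; 0.803), oxidative stress genes 0.808 and 0.595 (0.0113 and 0.132, adjusted p = 0.0327; 0.304; 0.836) and p53 targets 0.779 and 0.5 (0.0155 and 0.216, adjusted p = 0.0373; 0.0338; 0.763), in the same order. Cell cycle genes also went the other way but missed the threshold, with r = -0.739 and rho = -0.476 (exact permutation p = 0.0354 and 0.243, adjusted p = 0.0789). Without the same rats r was 0.369, and with slide means removed -0.715.

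The test planned for a hypothesis on the reference asked whether treated prostates may lie closer to normal prostate. For 200 genes above and 200 below the reference, picked on the control rats of the other slide, the score of treated rats differed from that of control rats by -0.58 on slide 1 and -0.20 on slide 2, a mean of -0.39. The exact two-sided permutation p within slides was 0.0556, which is the smallest that 36 assignments can give, so the design cannot reach the threshold. The genes were not picked again for each assignment, so this p takes the scores as fixed. With scaling between arrays the difference was -0.27, and it lay between -0.57 and -0.26 with 1 rat left out. The scores were 7.22 and 6.74 in Control 102 and 103, 7.0 and 7.06 in Control 104 and 106, 6.15 and 6.66 in Telmisartan 302 and 303, and 6.93 and 6.72 in Telmisartan 305 and 306. A shift towards the reference cannot be told apart from the immune variation between rats or from the array position, since immune genes lie above the reference and position follows the group.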
